A study of Arachis hypogaea with 16 samples.

How the data were processed

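Leaf RNA of 2 peanut (Arachis hypogaea) genotypes was measured on 16 oligonucleotide arrays with 2 colours, which makes 32 labelled samples. Per the labels' protocols, RNA came from a plant RNA kit and was amplified and labelled with an Agilent linear amplification kit, with Cy3 in channel 1 and Cy5 in channel 2. Each array held 15744 spots, of which 536 were control spots and 15208 were spots of 14352 distinct probes of 60 bases. Per the file headers, the arrays lay on 2 slides of 8 arrays each, and each slide was scanned apart from the other.

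The deposited scanner files give, per spot and channel, the mean intensity, the median local background intensity and a processed signal, as Agilent Feature Extraction (version 9.5, per the submitters' processing notes) wrote them. The deposited files also give a log10 ratio of Cy5 over Cy3 per spot, and flags for spots that were non-uniform, saturated or well above background. The deposited value table of the whole series held the same log10 ratio for each of the 16 arrays, with a largest difference of 0.005 from the scanner files, so its scale and its direction (Cy5 over Cy3) are settled. Each of its column medians was 0.

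The 32 samples belong to 16 conditions, formed by 2 genotypes, 2 pretreatments and 4 time points. Each condition had 2 samples, numbered replicates 1 and 2 in the labels and carried by different dyes, and the arrays formed a closed loop. The design text speaks of 3 replications, while the labels used here number 2. Nothing in the labels says that replicates came from separate plants, so p-values measure the spread between these samples, which may be technical. Slide and replicate number nearly coincided, since 14 of the 16 samples on slide 1 were numbered 1 and 2 were numbered 2. Replicate number was not used as a block in the reported tests. All 16 acclimated samples were labelled as grown in a walking chamber, against 5 of the 16 non-acclimated samples; the other 11 were labelled greenhouse. In COC166 non-acclimated, replicate 1 came from the chamber and replicate 2 from the greenhouse at every time point, so place and replicate cannot be told apart there.

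Intensities were background-corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, normalised by loess within arrays with control spots given no weight, and scaled between arrays by Aquantile. Spots with a non-uniformity flag were left out, and the spots of a probe were averaged. A probe was tested where at least 4 of the 32 samples were well above background, which left 6830 probes; 8 more passed this filter but lost too many spots to the flags to be fitted, and 6412 of the 14352 probes were above background in no sample. The log2 signals of both channels entered 1 linear model with a mean per condition, a dye term and a common correlation of 0.414 between the channels of a spot. Moderated tests came from limma's eBayes, with 15 residual and 2.71 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Comparisons over time, genotype and pretreatment were averages of condition means. Heat within a combination of genotype and pretreatment was the mean of day 2 and day 7 minus day 0.

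Median intensities were 38.9 to 45.8 in Cy3 and 43.5 to 55.7 in Cy5, over median backgrounds of 35 to 40.5 and 34 to 39. Between 35.0% and 48.1% of the probe spots of a sample were well above background, and the number of arrays limits the precision of every value. The offset of 50 shrinks log2 differences of dim probes: among probes that passed, log2 differences from Agilent's processed signals were a median of 1.65 times as large at day 2 and 1.83 times as large at recovery. Where a probe was above background in no sample of a group, the difference is given as a bound, from the bright group's mean log2 signal against the mean, per sample, of the higher of the probe's own signal and the lowest signal well above background.

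A pair of summary indices describe each sample. The probes of the heat index were those that differed between heated and day 0 samples in the other 3 combinations of genotype and pretreatment. The index is the mean log2 signal of the probes that rose minus that of the probes that fell, scaled so that 0 is the mean of those combinations' day 0 samples and 1 that of their heated samples. A recovery index was formed in the same way from recovery against day 0.

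The probes carry no gene names: 0 probes had a description other than "Unknown", and 0 probe IDs were found in the 110961 rows of the gene table used as reference. The 22 gene lists fixed before the data were examined could therefore not be tested, and no genome position was assigned. By the rule fixed for that case, at most 2 probes that rose and 2 that fell are named per comparison, those with the largest log2 difference past the threshold; where fewer than 5 probes passed, those with the lowest p are named and said not to pass.

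The test was tried on simulated data with 6738 probes, real means, spreads and channel correlation, and 200 changed probes. For day 2 against day 0 it recovered 85.1% of changes of 0.5 on the log2 scale, 97% of changes of 1 and 100% of changes of 2, and 6.93% of its calls were false. For acclimated against non-acclimated it recovered 88.1% of changes of 0.5. For heat within 1 combination it recovered 37.3% of changes of 0.5, 77.6% of changes of 1 and 93.9% of changes of 2. The simulated noise was independent between probes, so deviations of a whole sample across many probes were not simulated. The rates hold for independent noise only.

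The alternatives fixed before the data were examined were Agilent's processed signals, no background subtraction, quantile scaling between channels, no filter and a stricter filter (16 of 32 samples) on dim probes, flagged spots kept, no dye term, log ratios alone with pairwise interactions, the deposited value table under that model, slide as a block, replicate number as a block, growth place as a covariate, and each array left out in turn. A normexp offset of 5, the contrasts without the COC041 acclimated samples, fits within each slide, and the comparisons of day 7 with day 2 and of recovery with day 7 were added after seeing the data. Fits within a slide used its 16 samples and terms for genotype, pretreatment, time and dye alone, without a mean per condition. Their counts are therefore not like for like with the reported ones. The model for log ratios alone and the deposited value table has no term for genotype, pretreatment and time together. It also leaves fewer residual degrees of freedom than the 15 of the reported model. A low count from it does not show an absence of change.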

Results

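Transcript levels were measured in peanut leaves of COC041, labelled heat-tolerant, and COC166, labelled susceptible. The series asked how acquired thermotolerance, the gain in heat tolerance that follows a milder or earlier exposure, alters the response to heat. Acclimated plants were held at 45 °C for 1 day and returned to ambient conditions for 7 days before stress; non-acclimated plants went into stress directly. Stress began 45 days after sowing. Leaves were taken just before it (day 0, 45 days after sowing), after 2 days (47 days after sowing), after 7 days (52 days after sowing) and in recovery, 3 days after 14 days of stress (62 days after sowing). Each of the 16 conditions had 2 samples, which gives 8 samples per time point, 16 per genotype and 16 per pretreatment.

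Of 14352 probes, 6830 were bright enough to be tested. Replicates of a condition correlated over the tested probes with r between 0.845, in COC041 non-acclimated day 0, and 0.974, and samples of different conditions with a median r of 0.877 and a highest r of 0.982. In 1 of the 16 conditions, COC041 acclimated day 7, each replicate was the other's nearest sample. The first principal component held 37.9% of the variance and set the 8 recovery samples apart, together with replicate 1 of COC166 acclimated day 2. The second component held 22.4%, with most heated samples at its lower end and the day 0 samples of COC166 non-acclimated and replicate 1 of COC166 acclimated and COC041 non-acclimated day 0 at its upper end. Probes are given by their identifiers, since no gene name is attached to them.

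**Figure D1:**
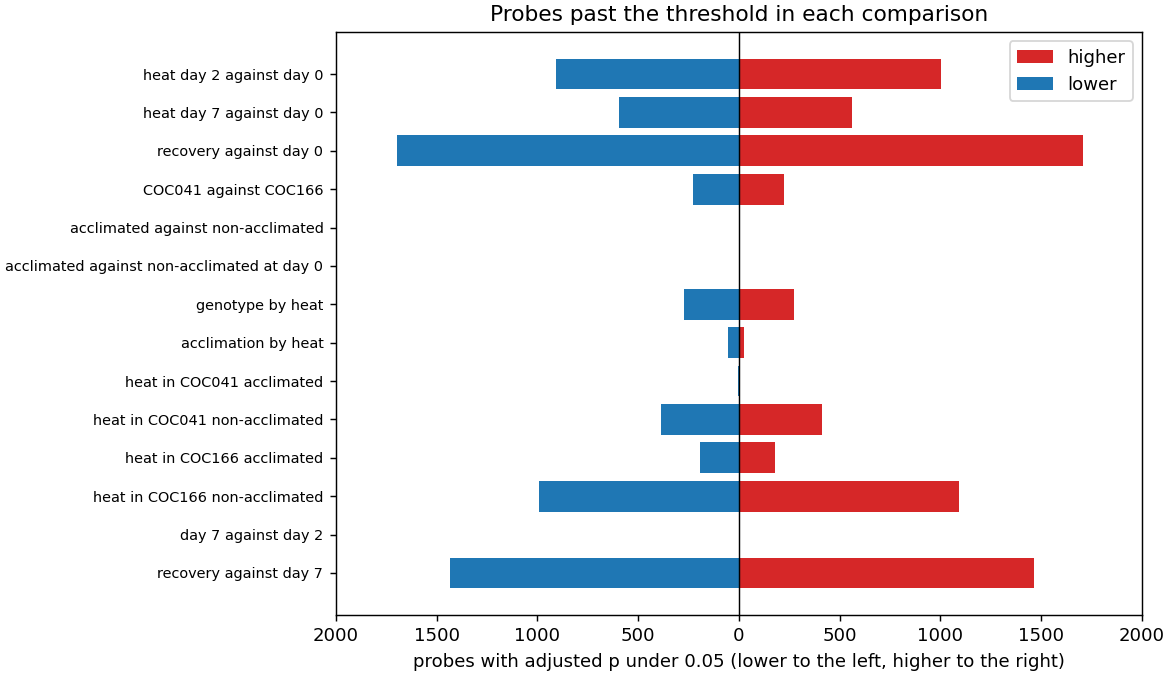
Number of probes with an adjusted p under 0.05 in each comparison, with probes that were lower drawn to the left and probes that were higher drawn to the right. Recovery against day 0 has the longest bars, with 1707 probes higher and 1697 lower, and acclimated against non-acclimated has none.

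The first question was what changed after 2 days of heat, averaged over both genotypes and pretreatments. Day 2 and day 7 plants were 47 and 52 days old, against 45 at day 0. No unstressed plants of those ages were among the samples. Heat and age therefore cannot be told apart in any comparison of heated with day 0 samples. Probe AH2V12915 (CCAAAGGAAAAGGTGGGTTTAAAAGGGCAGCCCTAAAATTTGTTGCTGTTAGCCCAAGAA) rose from a mean log2 signal of 7.67 ± 2.36 (SD, n = 8) at day 0 to 12.05 ± 0.86 (SD, n = 8) at day 2, a difference of 4.44 ± 0.46 (SE; adjusted p = 1.23e-05). AH2V25057 (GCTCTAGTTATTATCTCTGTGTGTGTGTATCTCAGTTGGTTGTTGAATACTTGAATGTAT) rose by 3.65 ± 0.35 (SE; adjusted p = 5.47e-06), or 12.6-fold. AH2V47073 (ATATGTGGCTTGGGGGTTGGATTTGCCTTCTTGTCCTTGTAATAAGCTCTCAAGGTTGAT) fell by 3.69 on the log2 scale (SE 0.31, adjusted p = 1.45e-06), and every day 2 sample lay below every day 0 sample. AH2V19187 fell by 2.80 (SE 0.22, adjusted p = 1.06e-06), from 11.73 ± 0.91 (SD, n = 8) to 8.84 ± 0.71 (SD, n = 8). In all, 1911 of the 6830 probes changed, 1004 up and 907 down, and 208 of them changed at least 2-fold, against 937 by Agilent's processed signals. With the slide as a block 1816 probes passed. Within slide 1 the count was 528, and within slide 2, which held 3 of the 8 day 0 samples, it was 3. The count was 1116 without the array of COC166 acclimated recovery and day 0, both replicate 1, 1268 without the array of COC166 non-acclimated day 2 and day 0, both replicate 2, and 0 from log ratios alone or the deposited value table.

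**Figure D2:**
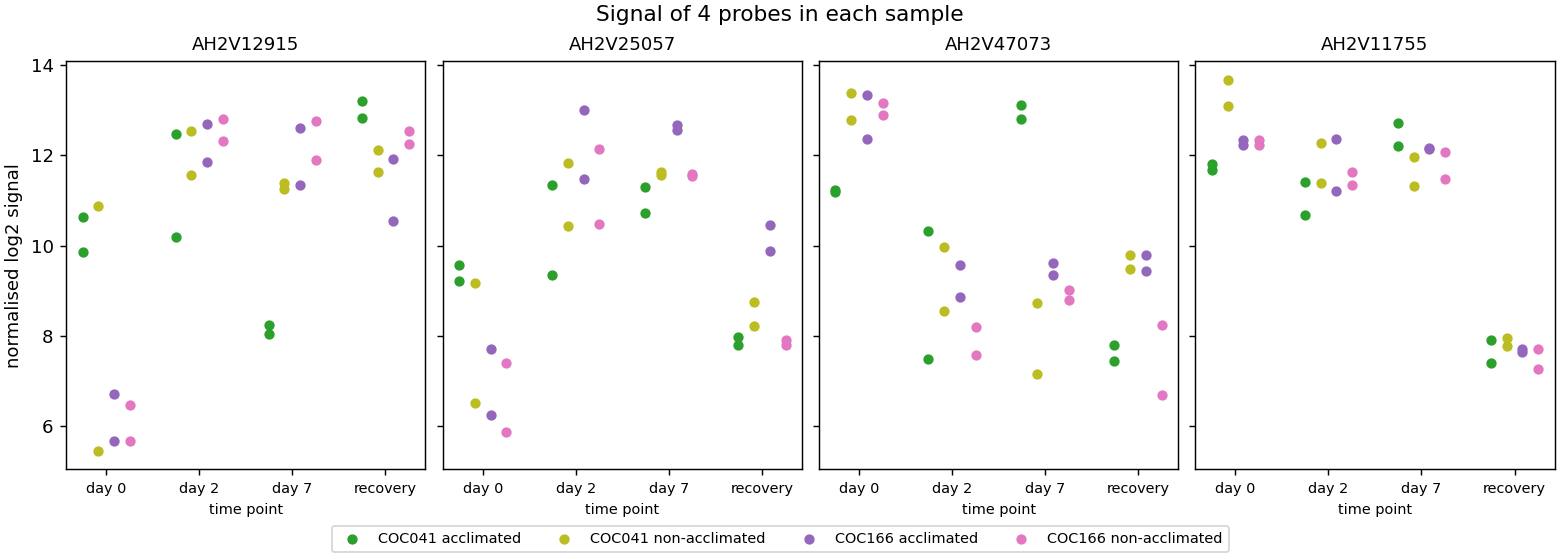
Normalised log2 signal of 4 probes in each of the 32 samples, by time point, with 1 colour per combination of genotype and pretreatment and 1 point per sample. AH2V12915 rises from a mean of 7.67 at day 0 to 12.05 at day 2, AH2V47073 falls from 12.54 to 8.82, and AH2V11755 drops at recovery to 7.68.

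After 7 days of heat AH2V25057 was 4.05 ± 0.38 (SE) log2 units above day 0 (adjusted p = 6.6e-06), and its 8 day 7 samples all lay above the 8 day 0 samples. AH2V12915 was 3.15 ± 0.50 (SE) above day 0 (adjusted p = 0.000576), and 4.84 without the COC041 acclimated samples, in which it went from 9.85 and 10.64 at day 0 to 8.05 and 8.24 at day 7. AH2V16704 fell by 2.58 (SE 0.31, adjusted p = 8.31e-05). AH2V31036 fell by 2.59 (SE 0.34, adjusted p = 0.000128) to a level well above background in 2 of 8 samples; processed signals gave -5.23, so the size is uncertain. The count of changed probes was 1155, with 561 up and 594 down, and 1004 with the slide as a block; within slide 1 it was 49 and within slide 2 it was 2. It was 2125 without the array of COC041 non-acclimated day 0 and COC041 acclimated day 2, both replicate 2. It was 352 without the array of COC166 non-acclimated day 0 and day 7, both replicate 1, 592 without that of COC166 acclimated recovery and day 0, both replicate 1, and 621 without that of COC041 acclimated recovery and day 7, both replicate 1. It was 726 without the array of COC041 non-acclimated day 2 and day 0, both replicate 1, 652 without that of COC166 acclimated day 7 and COC041 non-acclimated recovery, both replicate 2, and 620 without that of COC041 acclimated day 0 and recovery, both replicate 2. Without all COC041 acclimated samples 2273 probes passed. Log ratios alone or the deposited value table gave 0, at day 7 as at day 2, but those fits leave fewer residual degrees of freedom.

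The day 2 and day 7 responses were set side by side. Of the 1004 probes that rose at day 2, 404 also rose at day 7, against 82.5 for independent lists, and of the 907 that fell, 496 also fell, against 78.9. No probe passed in opposite directions. The correlation of the log2 differences across 6738 probes, which are not independent replicates, was 0.89, against 0.51 in simulated data without any effect that shared the day 0 samples; with the day 0 samples split between the comparisons it was 0.75. The covariance was 0.125, against 0.00846 in the simulation and 0.107 with the day 0 samples split. In the direct comparison of day 7 with day 2, added after seeing the data, limma called 0 of the 6830 probes, while 840 had an unadjusted p under 0.05 and Agilent's processed signals gave 54. AH2V38018, with the lowest p, was 0.34 ± 0.06 (SE) higher at day 7 (adjusted p = 0.0555) and above background in 4 of 8 day 7 and 2 of 8 day 2 samples. AH2V16934, with the lowest p among probes lower at day 7, differed by -0.38 ± 0.07 (SE; adjusted p = 0.0589). Neither passed, but with processed signals both did, at 1.23 and -0.61 (adjusted p = 0.0402 for each). The slide block gave 8 probes, and each slide alone gave 0. Single arrays also moved this count: it was 148 without that of COC041 non-acclimated day 2 and day 0, both replicate 1, 134 without that of COC041 non-acclimated day 0 and COC041 acclimated day 2, both replicate 2, and 47 without that of COC166 non-acclimated day 7 and COC166 acclimated day 2, both replicate 2. It was 7 without the array of COC166 acclimated day 2 replicate 1 and recovery replicate 2, 6 without that of COC041 non-acclimated day 7 and COC166 non-acclimated recovery, both replicate 2, 2 without that of COC041 acclimated day 7 replicate 2 and COC166 acclimated day 7 replicate 1, and 1 without that of COC166 acclimated day 7 and COC041 non-acclimated recovery, both replicate 2.

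Recovery samples, taken 3 days after the end of stress, differed most from day 0. AH2V15855 (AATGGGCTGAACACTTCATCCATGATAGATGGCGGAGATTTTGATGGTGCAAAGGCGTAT) rose from 6.85 ± 0.79 (SD, n = 8) to 13.25 ± 0.63 (SD, n = 7), a fitted difference of 6.18 ± 0.41 (SE; adjusted p = 8.68e-09), and was well above background in 5 of 8 day 0 samples. AH2V11755 (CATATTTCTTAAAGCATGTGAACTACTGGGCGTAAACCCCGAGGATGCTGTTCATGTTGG) fell by 4.77 (SE 0.15, adjusted p = 2.65e-13), from 12.42 ± 0.66 (SD, n = 8) to 7.68 ± 0.24 (SD, n = 8). AH2V16796 fell by 4.45 (SE 0.24, adjusted p = 4.08e-10). AH2V12915 was 4.46 ± 0.47 (SE) above day 0 (adjusted p = 4.73e-07). At recovery 3404 probes differed from day 0, 1707 higher and 1697 lower, and 679 at least 2-fold, against 1945 by processed signals. The slide block gave 3392, slide 1 alone 1720 and slide 2 alone 1709. Recovery plants were 62 days old against 45 at day 0, and no unstressed plants of that age were among the samples, so age and recovery cannot be told apart.

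Recovery was also compared with day 7, a comparison added after seeing the data. AH2V43409 was 4.62 ± 0.25 (SE) higher in recovery (adjusted p = 7.18e-10) and AH2V15855 5.51 ± 0.40 (SE) higher (adjusted p = 2.06e-08). AH2V25943 fell by 4.84 (SE 0.19, adjusted p = 7.58e-12) and AH2V34699 by 4.34 (SE 0.19, adjusted p = 2.69e-11). In this comparison 2898 probes passed, 1466 higher and 1432 lower, with 2890 under the slide block, 44 within slide 1 and 1555 within slide 2. Of the 1004 probes that rose at day 2, 700 were also higher than day 0 at recovery, against 250.9 for independent lists, and of the 907 that fell, 656 were lower, against 225.4. The correlation of day 2 with recovery differences was 0.59, against 0.53 in simulated data without any effect and 0.52 with the day 0 samples split. For day 7 with recovery it was 0.46, against 0.55 and 0.38. The simulated correlation comes from noise alone, so it is no baseline for differences that hold effects. The covariance is the better guide. For day 2 with recovery it was 0.156, against 0.00842 in the simulation and 0.133 with the day 0 samples split. For day 7 with recovery it was 0.108, against 0.00928 and 0.087. Most of the covariance thus stayed when the day 0 samples were not shared, though part of the overlap in calls may come from sharing them.

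The genotypes were compared over all time points and pretreatments. AH2V15937 (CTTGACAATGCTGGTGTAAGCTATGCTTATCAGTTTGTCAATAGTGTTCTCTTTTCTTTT) was at least 13.3-fold higher in COC041, where it was well above background in 16 of 16 samples, than in COC166, where it was above background in 0 of 16 (adjusted p = 4.78e-14). AH2V14773 (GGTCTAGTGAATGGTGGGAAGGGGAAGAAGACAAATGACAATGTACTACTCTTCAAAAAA) was at least 10.8-fold higher in COC041 (adjusted p = 4.44e-14), again with 16 against 0 samples above background. AH2V31038 was lower in COC041, with a log2 difference of -3.86 ± 0.22 (SE; adjusted p = 7.97e-10), or -6.63 by processed signals; it was above background in 8 of 16 COC041 samples, so the size is uncertain. AH2V32132 was lower by a difference of -3.70 ± 0.30 (SE; adjusted p = 6.33e-08). The genotypes differed in 451 probes, 224 higher and 227 lower in COC041, and 34 at least 2-fold, against 202 by processed signals. A further count took probes above background in at least 14 of 16 samples of 1 genotype and at most 2 of 16 of the other: 12 were found for COC041 and 10 for COC166, against at most 0 in 100 random regroupings. With the slide as a block 477 probes passed, within slide 1 there were 92 and within slide 2 there were 188, and 293 passed without the array of COC166 acclimated day 0 replicate 2 and COC041 acclimated day 0 replicate 1. The count was 8 from log ratios alone, 17 from the deposited value table and 221 without the COC041 acclimated samples. A probe that binds differently to the 2 genotypes' sequences would give the same readout as a difference in transcript level.

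Acclimated and non-acclimated plants were then compared over all samples. No probe passed: limma called 0 of 6830, with 325 at an unadjusted p under 0.05, and Agilent's processed signals also gave 0. AH2V35632, with the lowest p among probes higher in acclimated plants, differed by 0.25 ± 0.06 (SE; adjusted p = 0.944), and AH2V15556, with the lowest p among those lower, by -0.27 ± 0.07 (SE; adjusted p = 0.944). Just before stress, 7 days after acclimation had ended, 0 probes passed with limma, 791 had an unadjusted p under 0.05 and processed signals gave 1. AH2V46099 was lower in acclimated plants at that point, at -1.29 ± 0.21 (SE; adjusted p = 0.0633), and AH2V26559 was higher, at 1.00 ± 0.22 (SE; adjusted p = 0.214); neither passed. Over all samples the slide block and each slide alone also gave 0, and at day 0 the slide block gave 1, AH2V46099 (-1.37, adjusted p = 0.0167). Without the array of COC041 non-acclimated day 0 and COC041 acclimated day 2, both replicate 2, 869 probes passed at day 0 and 25 over all samples, and without that of COC166 non-acclimated day 7 and COC166 acclimated day 2, both replicate 2, 1 passed over all samples. Growth place was confounded in part with pretreatment, since the 16 acclimated samples came from the walking chamber and 11 of 16 non-acclimated samples from the greenhouse.

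Heat responses were next taken within each combination, as 4 heated samples against 2 at day 0. In COC166 non-acclimated, AH2V12915 rose by 6.49 ± 0.73 (SE; adjusted p = 1.57e-05), AH2V41241 rose at least 26.7-fold from a level above background in 0 of 2 day 0 samples (adjusted p = 0.000173), and AH2V47073 fell by 4.70 (SE 0.48, adjusted p = 8.15e-06). In COC166 acclimated, AH2V12915 rose by 6.09 ± 0.84 (SE; adjusted p = 0.000758), AH2V25057 by 5.62 ± 0.64 (SE; adjusted p = 0.000166), AH2V47073 fell by 3.56 (SE 0.56, adjusted p = 0.00197) and AH2V19187 fell by 3.49 (SE 0.41, adjusted p = 0.000166). Without the array of COC166 acclimated recovery and day 0, both replicate 1, AH2V12915 (5.85, adjusted p = 0.0931), AH2V25057 (4.70, adjusted p = 0.051) and AH2V47073 (-2.93, adjusted p = 0.247) did not pass. In COC041 non-acclimated, AH2V25057 rose by 3.79 ± 0.59 (SE; adjusted p = 0.00343) and AH2V47073 fell by 3.83 (SE 0.52, adjusted p = 0.00135). AH2V25057 stood at 6.52 and 9.17 in the day 0 replicates. Without the array of COC041 non-acclimated day 2 and day 0, both replicate 1, neither passed: the rise was 3.19 (adjusted p = 0.223) and the difference of AH2V47073 -4.42 (adjusted p = 0.0807). In COC041 acclimated, AH2V16801 rose by 2.28 ± 0.38 (SE; adjusted p = 0.0273). AH2V40584 rose by a fitted 1.82 ± 0.32 (SE; adjusted p = 0.0305) on the log2 scale, or 3.52-fold. It was above background in 3 of 4 heated and 0 of 2 day 0 samples. Its group means gave a bound of 4.18-fold, above the fitted value, and processed signals a log2 difference of 4.70, so the size is uncertain. AH2V33231 (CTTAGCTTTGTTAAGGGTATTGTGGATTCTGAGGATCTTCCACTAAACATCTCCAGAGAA) and AH2V19883 (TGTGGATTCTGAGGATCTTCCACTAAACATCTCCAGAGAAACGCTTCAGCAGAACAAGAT), share 40 bases. The former fell by 1.98 (SE 0.26, adjusted p = 0.00368) and the latter fell by 1.73 (SE 0.35, adjusted p = 0.0482), but the latter did not pass with the slide as a block (adjusted p = 0.0694) or with processed signals (0.103). Single arrays left out ended the call of AH2V16801 in 7 cases, of AH2V40584 in 10, of AH2V33231 in 2 and of AH2V19883 in 13. The highest adjusted p among these was 0.371, 0.567, 0.0899 and 0.733, each without the array of COC041 acclimated day 0 and recovery, both replicate 2.

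The number of probes that changed with heat was 2089 in COC166 non-acclimated, 797 in COC041 non-acclimated, 375 in COC166 acclimated and 14 in COC041 acclimated. Of the 1095 probes that rose in COC166 non-acclimated, 95.9% had a positive difference in COC041 non-acclimated and 94.6% in COC166 acclimated, but 33.5% in COC041 acclimated, where their mean difference was -0.17. Their mean was 0.57 in COC041 non-acclimated, 0.56 in COC166 acclimated and 0.90 in COC166 non-acclimated, where they were chosen. Of the 994 that fell, 93.7%, 96.3% and 39.2% had a negative difference in those combinations. The COC166 non-acclimated count was 313 without the array of its day 0 and day 7 replicate 1 samples, 620 without that of its day 2 and day 0 replicate 2 samples and 1217 from the deposited value table. The COC041 non-acclimated count was 0 without the array of its day 2 and day 0 replicate 1 samples, 421 without that of its recovery replicate 1 and day 2 replicate 2 samples, and 2001 without that of its day 0 and COC041 acclimated day 2, both replicate 2. That last array gave 774 for COC166 acclimated when left out, whose count was 5 without the array of its recovery and day 0 replicate 1 samples, 236 without that of its day 0 replicate 2 and COC041 acclimated day 0 replicate 1, 150 without that of its day 7 and COC041 non-acclimated recovery, both replicate 2, and 762 without that of COC041 non-acclimated day 2 and day 0, both replicate 1. The COC041 acclimated count was 0 without the array of COC166 acclimated day 0 replicate 2 and COC041 acclimated day 0 replicate 1, and 40 without that of COC041 non-acclimated day 2 and day 0, both replicate 1. It moved by over 1.5 times without 13 of the 16 arrays; the exceptions were those of COC166 acclimated recovery and day 0, both replicate 1, of COC041 non-acclimated day 0 and COC041 acclimated day 2, both replicate 2, and of COC041 non-acclimated day 7 and COC166 non-acclimated recovery, both replicate 2. The slide block gave 2028, 753, 182 and 14 probes in the same order, and a slide held too few samples of a combination for a value within it.

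**Figure D3:**
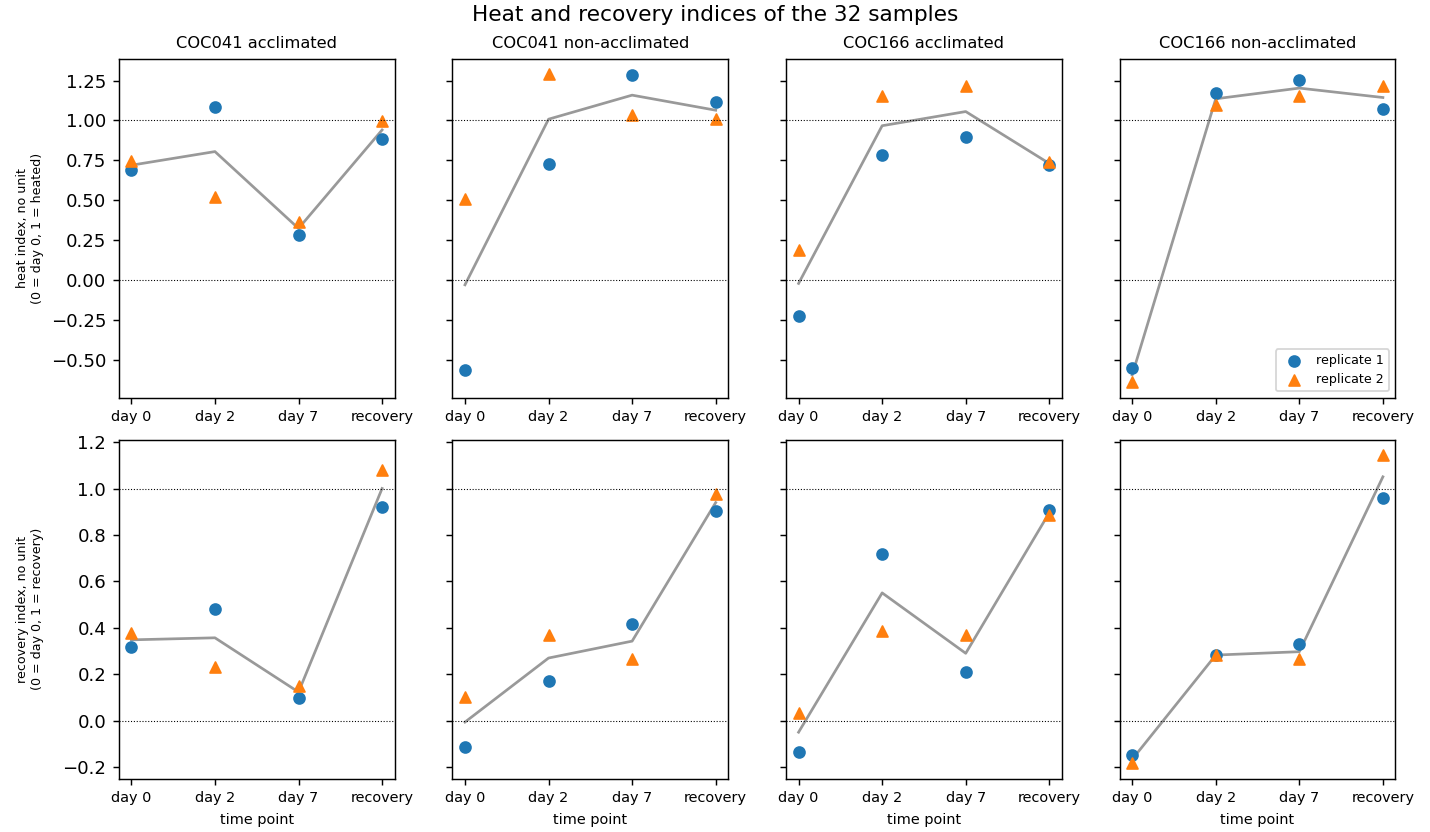
Heat index (top, no unit) and recovery index (bottom, no unit) of each sample by time point, for the 4 combinations, with circles for replicate 1, triangles for replicate 2 and lines through the means. In COC041 acclimated the heat index is 0.72 at day 0 and 0.32 at day 7, whereas in COC166 non-acclimated it goes from -0.60 to 1.20.

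The heat index, built for each combination from the other 3, summarised these profiles. In COC166 non-acclimated it was -0.60 at day 0, 1.14 at day 2 and 1.20 at day 7, and in COC166 acclimated it was -0.02, 0.97 and 1.06. In COC041 acclimated it was already 0.72 at day 0 (0.69 and 0.75 in the replicates), 0.80 at day 2 (1.09 and 0.52) and 0.32 at day 7 (0.28 and 0.36). In COC041 non-acclimated the day 0 replicates lay at -0.57 and 0.50, and the means at day 2 and day 7 were 1.01 and 1.16. Recovery samples, no longer under stress, also had high mean heat indices. These were 0.94 in COC041 acclimated, 1.06 in COC041 non-acclimated, 0.73 in COC166 acclimated and 1.14 in COC166 non-acclimated. A high heat index is thus not particular to heated samples. The recovery index of the 8 recovery samples was 0.89 to 1.14, and that of COC166 acclimated day 2 replicate 1 was 0.72, against 0.38 in replicate 2.

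Whether heat acted differently in the genotypes was tested as the heat difference in COC041 minus that in COC166. AH2V12915 had the most negative value, -4.99 ± 0.76 (SE; adjusted p = 0.00157), with heat differences of -0.67 in COC041 acclimated, 3.27 in COC041 non-acclimated, 6.09 in COC166 acclimated and 6.49 in COC166 non-acclimated. The 3.27 rests on day 0 replicates at 5.46 and 10.86. It was 0.92 (adjusted p = 0.881) without the array of COC041 non-acclimated day 2 and day 0, both replicate 1, and 5.78 without that of COC041 non-acclimated day 0 and COC041 acclimated day 2, both replicate 2. AH2V16227 followed at -3.40 ± 0.63 (SE; adjusted p = 0.00474), or -2.08 without the latter array. AH2V24298 had heat differences of -4.43 in COC166 non-acclimated, -3.43 in COC166 acclimated, -0.80 in COC041 non-acclimated and -0.23 in COC041 acclimated, an interaction of 3.42 ± 0.72 (SE; adjusted p = 0.00791), which did not pass without the latter array (2.40, adjusted p = 0.0843) or that of COC166 non-acclimated day 0 and day 7, both replicate 1 (2.64, adjusted p = 0.0816). AH2V23725 had an interaction of 2.83 ± 0.50 (SE; adjusted p = 0.00351). The interaction passed for 545 probes, 272 positive and 273 negative, and for 409 with the slide as a block. It passed for 0 from log ratios alone and for 11 without the COC041 acclimated samples, a contrast of the non-acclimated combinations only. There the SE of the 545 probes had a median of 0.28 against 0.20, and their difference one of 0.62 against 0.87. Of them 544 kept their direction, but they were chosen on the full contrast, which contains this one, so that is largely built in. None of the named probes passed in the contrast of the non-acclimated combinations. Values were 3.63 for AH2V24298 (adjusted p = 0.198), 3.45 for AH2V23725 (0.0552), -3.22 for AH2V12915 (0.326) and -2.11 for AH2V16227 (0.529). With the larger SE, the lost calls do not show that the interaction came from COC041 acclimated alone. Without the array of COC041 non-acclimated day 0 and COC041 acclimated day 2, both replicate 2, 97 passed, and without that of COC041 non-acclimated day 2 and day 0, both replicate 1, 1059 passed. The count was 111 without the array of COC166 non-acclimated day 0 and day 7, both replicate 1, 188 without that of COC166 acclimated recovery and day 0, both replicate 1, 290 without that of COC166 non-acclimated day 2 and day 0, both replicate 2, and 273 without that of COC041 acclimated day 0 and recovery, both replicate 2.

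Whether heat acted differently after acclimation was tested in the same way. AH2V33627 had an interaction of 1.52 ± 0.34 (SE; adjusted p = 0.0411) and AH2V40551 one of 1.52 ± 0.28 (SE; adjusted p = 0.0297). AH2V16215 had an interaction of -2.004 ± 0.40 (SE; adjusted p = 0.0297), from heat differences of -1.91 in COC041 acclimated, 0.99 in COC041 non-acclimated, 1.23 in COC166 acclimated and 2.35 in COC166 non-acclimated, and AH2V18592 had one of -1.80 ± 0.39 (SE; adjusted p = 0.0361). In all 81 probes passed, 25 positive and 56 negative, and the share that was positive was 30.9%. With quantile scaling it was 51.6% of 62, of which 49 were among the 81. Without the COC041 acclimated samples the 81 had a median size of 0.63 in the reported direction, against 0.95. Their median SE was 0.25 against 0.19, so calls lost there do not show an absence of effect. The call was not stable: 12 probes passed with processed signals, none of the 4 named among them, 0 without a dye term, 228 with the slide as a block, 33 with growth place as a covariate and 0 without the COC041 acclimated samples, and 15 of the 16 arrays moved the count by over 1.5 times when left out singly. The exception was the array of COC166 acclimated recovery and day 0, both replicate 1; the lowest count was 0 and the highest 1158, the latter without that of COC041 non-acclimated day 0 and COC041 acclimated day 2, both replicate 2.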

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

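The tests of the 3 patterns below were chosen after the results had been seen. Tests of the difference itself passed for 545 probes for genotype by heat and for 81 for acclimation by heat. The latter call was not stable, with 12 probes from Agilent's processed signals and 0 without a dye term. Without the COC041 acclimated samples, where standard errors were larger, 11 and 0 probes passed. Both counts also moved widely when single arrays were left out. The named probes of these tests had interactions of 3.42 (AH2V24298), 2.83 (AH2V23725), -4.99 (AH2V12915) and -3.40 (AH2V16227) for genotype, and of 1.52 (AH2V33627), 1.52 (AH2V40551), -2.004 (AH2V16215) and -1.80 (AH2V18592) for acclimation. Among the 8 samples of day 7, COC041 non-acclimated replicate 1 stood apart with 35.2% of its spots well above background. The other channel of its array, COC041 acclimated day 2 replicate 1, had 35.0%, the lowest of the 32 samples, so both channels of that array were low. The day 7 sample was the 1 such sample in 12 sets of samples examined, and chance gives about 1 in 20.

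COC041 acclimated samples showed little heat difference, with a heat index of 0.72 at day 0 and 0.32 at day 7. If day 0 and day 7 labels had been exchanged there and the response were like that of the other combinations, the COC166 non-acclimated heat probes would move the same way as in those; after the exchange 74.5% did, against 36.2% as labelled and 94.8% and 95.4% in COC041 non-acclimated and COC166 acclimated, which argues against this as the whole cause. The chamber-grown COC166 acclimated samples had a heated minus day 0 index of 1.03, so the walking chamber did not remove the heat difference in that genotype. In COC041 all acclimated samples came from the chamber, and 7 of the 8 non-acclimated samples came from the greenhouse. Place and acclimation therefore cannot be told apart in COC041. A candidate biological explanation is heat-like expression kept after acclimation in COC041. The heat index was also 0.73 to 1.14 in the recovery means, and 0.50 in COC041 non-acclimated day 0 replicate 2. A high index is thus not particular to heat or to acclimation. The index at day 7 minus day 0 was -0.396, which a later decline would also give. Kept expression therefore cannot be told apart from an exchange with a smaller response. What keeps this open is that no sample before acclimation was analysed here.

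The day 0 replicates of COC041 non-acclimated lay at -0.57 and 0.50 on the heat index, and replicate 2 shared its array with COC041 acclimated day 2 replicate 2. An exchange of the array's samples between dyes would turn its log ratios against the difference between the other replicates. The slope was -0.0515, where 8 arrays with a large expected difference had slopes of 0.66 to 0.84. So flat a slope goes with neither the labelled nor the exchanged order. The array's samples had heat indices of 0.50 and 0.52, so the slope cannot decide on an exchange. A sample of the other genotype is excluded, since 84.6% of the probes seen in COC041 and not in COC166, chosen without replicate 2, were above background in it. A weak hybridisation does not account for it either, with 38.0% of spots well above background against 35.0% to 41.9% in the other Cy3 samples. A partly heated or partly mixed sample and a difference between plants stay open, and were not tested.

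COC166 acclimated day 2 replicate 1 had a recovery index of 0.72, against 0.38 in replicate 2, and shared its array with COC166 acclimated recovery replicate 2. Equal mixing with that sample would have lowered the recovery sample as well, but its index was -0.022 from that of its replicate, against a difference of 0.332 between the day 2 replicates. An exchange with a recovery sample needs a partner out of place, and the lowest index among the recovery samples was 0.885, against at most 0.48 in the rest. For a recovery sample under a wrong label, 328 probes that set the recovery samples apart from all other times at least 2-fold were chosen without this sample. Of these, 14.0% lay nearer the other times in it. The share was at most 1.2% in recovery samples placed in the same way, and 97.9% in replicate 2 of its condition. Its nearest sample was COC166 acclimated recovery replicate 1, at r = 0.954, against 0.909 with its replicate. It thus lay far nearer recovery than its replicate did, though less near than the recovery samples. A wrong label is therefore not excluded. Recovery RNA in part of the sample stays open and was not tested, nor was a biological explanation.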

How the results depend on the processing

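A normexp offset of 5 and the counts without the COC041 acclimated samples were chosen after seeing the data. Of 192 counts under the alternatives other than single arrays left out, 134 were within 1.5 times the reported count and 58 were not. For the 56 named results, 1439 of 1656 values under 30 alternatives stayed on the same side of the threshold, 178 were no longer past it, 39 came past it and 0 reversed. Direction was compared only where a result passed in the reported fit or in the alternative. The cause was not tested for any change below, except that log ratios alone and the value table leave fewer residual degrees of freedom.

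With Agilent's processed signals, counts became 1 for acclimation at day 0, 12 for acclimation by heat and 54 for day 7 against day 2. Log ratios alone gave 0 for day 2, day 7, genotype by heat, acclimation by heat, and heat in COC041 acclimated, COC041 non-acclimated and COC166 acclimated, but 1569 for recovery, 8 for genotype, 1336 for heat in COC166 non-acclimated and 1085 for recovery against day 7. The deposited value table gave 0 in the same places except 63 for genotype by heat, with 1742 for recovery, 17 for genotype, 1217 for heat in COC166 non-acclimated and 1686 for recovery against day 7. Growth place as a covariate gave 33 for acclimation by heat, 482 for heat in COC041 non-acclimated and 3 for day 7 against day 2. No background subtraction gave 938 for genotype by heat, 27 for heat in COC041 acclimated, 1362 for heat in COC041 non-acclimated and 76 for day 7 against day 2. Without a dye term the counts were 333 for genotype by heat, 0 for acclimation by heat and 9 for heat in COC041 acclimated. Without a filter they were 289, 4, 395 and 221 for genotype by heat, acclimation by heat, heat in COC041 non-acclimated and heat in COC166 acclimated, and the stricter filter gave 6 for heat in COC041 acclimated. An offset of 5 gave 214 for acclimation by heat, 5 for heat in COC041 acclimated and 9 for day 7 against day 2. Keeping spots marked non-uniform gave 2 for day 7 against day 2, and quantile scaling gave 38 there and 23 for heat in COC041 acclimated. Slide as a block gave 1 for acclimation at day 0, 228 for acclimation by heat, 182 for heat in COC166 acclimated and 8 for day 7 against day 2. Without the COC041 acclimated samples the counts were 2273 for day 7, 221 for genotype, 11 for genotype by heat, 0 for acclimation by heat and 1 for day 7 against day 2.

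The share of higher calls moved by over 10 percentage points in 4 cases among alternatives other than single arrays left out. For acclimation by heat it was 30.9%, against 51.6% with quantile scaling and 19.1% without background subtraction. For heat in COC041 non-acclimated it was 51.8%, against 41.6% with quantile scaling, and for genotype by heat 49.9%, against 39.7% in the value table. Single arrays left out moved it so in 6 cases, to between 34.7% and 62.4%. Cases with fewer than 20 calls were not compared.

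With the replicate block, 2 probes passed for acclimation at day 0, 565 for heat in COC166 acclimated and 2 for day 7 against day 2; the other 11 counts stayed within 1.5 times. Deviations of same-numbered samples from their condition means had a median correlation of 0.062 over 104 pairs of conditions that shared no array, with 42 over 0.1. The slide, which nearly coincided with the number, was run as a block of its own.

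Leaving out single arrays gave 1116 to 2643 probes for day 2, 352 to 2125 for day 7, 2623 to 3525 for recovery, 293 to 587 for genotype, 0 to 25 for acclimation, 0 to 869 for acclimation at day 0, 97 to 1059 for genotype by heat and 0 to 1158 for acclimation by heat. Heat in COC041 acclimated ranged from 0 to 40, in COC041 non-acclimated from 0 to 2001, in COC166 acclimated from 5 to 774 and in COC166 non-acclimated from 313 to 2305; day 7 against day 2 ranged from 0 to 148 and recovery against day 7 from 2159 to 3075. A condition left with 1 sample is taken to vary like the others. The gene lists and their estimated correlation were not run, since no probe has a gene name. Signal over background limits dim probes: 35.0% to 48.1% of spots were well above background.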

Other observations

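The tests in this part were chosen after the results had been seen. Genotype labels matched the data in 32 of 32 samples: of probes seen in 1 genotype and not in the other, chosen without the sample in question, at least 75% of those of a sample's own genotype were above background in it and at most 25% of those of the other.

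In COC041 acclimated the named heat probes did not all follow the index. AH2V47073 had log2 signals of 11.18 and 11.22 at day 0 and of 13.10 and 12.81 at day 7, whereas AH2V25057 had 9.21 and 9.58 at day 0 and 10.72 and 11.30 at day 7. With the day 0 and day 7 labels of COC041 acclimated exchanged, as a description only, 2389 probes passed at day 7, 2 for acclimation by heat and 123 for heat in COC041 acclimated. The genotype by heat count fell to 18.5% of the reported 545, and the heated minus day 0 index of COC041 acclimated went from -0.155 to 0.439.

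Other splits of the same samples tested whether counts of probes could come from chance. Time labels were exchanged among the samples of each genotype and pretreatment, genotype labels among those of each pretreatment and time point, and pretreatment labels among those of each genotype and time point. Where more than 100 splits exist, 100 were drawn, the real one included. For day 2 against day 0, 1 split gave as many as 1911 probes, the highest other being 1837; for recovery against day 0, 1 gave as many as 3404 (highest other 2539); for recovery against day 7, 1 gave as many as 2898 (highest other 701). For day 7 against day 0, 4 splits gave as many as 1155, with a highest other of 1751. That split exchanged the labels of all 4 COC041 acclimated samples and of 2 COC041 non-acclimated samples, which points to a structure of those samples. Genotype (451 probes, highest other 132) and genotype by heat (545 probes, highest other 215) were reached by 1 split each, and acclimation by heat (81 probes, highest other 115) by 2 splits. The share of splits was under 0.05 in these 7 comparisons, without adjustment for the number of comparisons. For day 7 against day 0 and acclimation by heat other splits gave higher counts, so chance is not excluded there. In the rest no other drawn split gave as many probes. This argues against chance for day 2 against day 0, both recovery comparisons and genotype. For genotype by heat, exchanged labels also mix the genotypes' difference over all time points into the spread, which by itself lowers the counts. The splits therefore cannot decide on chance for that interaction. Where the real count was 0 every split gives at least as many, so the splits say nothing about chance: 100 of 100 did for day 7 against day 2 (highest other 14) and for acclimated against non-acclimated (highest other 9). At day 0 the samples allow 18 splits, too few for a share under 0.05; all 18 gave at least the real count of 0, and the highest other was 4.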
